A study of Mus musculus with 11 samples.

How the data were processed

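Liver RNA from 11 male mice was measured, 5 wild type (WT) and 6 lacking Gsr (Gsr-null), on single-colour Affymetrix mouse arrays. Per the labels' protocols, total RNA was extracted with the RiboPure kit and labelled with biotin using the MessageAmp II kit, from 1 µg of RNA. The labels call the samples biological replicates of each genotype. The deposited table holds 1 value per probe set and sample, on a scale read here as log2 from its range and from its nearly equal quantiles across arrays. The authors used GCRMA, per the submitters' processing notes, a method that corrects background by probe sequence, normalizes between arrays and summarises probes into probe sets. Its version is not given in the sources used here, and neither are any filters, scan dates or batches. Scanner files were not used here. The number of arrays, 5 and 6, limits the precision of every value.

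The table held 22690 probe sets, of which 64 Affymetrix controls were left out of all tests. Of the other 22626, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none. The Entrez identifier of 20351 of those with 1 symbol was found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols differed from it. No genome build is named for the array, so no coordinates are given and the RefSeq table served only for names, chromosomes and the order of genes. No gene was named from a probe set with several symbols. Probe sets whose identifiers end in _s_at, _x_at or _a_at can bind several transcripts, so the values of genes measured by such probe sets may include related genes, among them Gstm3, Mmd2, H2aw, Mt1, Saa1, Saa2, Shmt1, Srxn1, Rrm2, Nnt, Cbs, Acot3, Fcgr2b and the MHC genes H2-Aa, H2-Ab1, H2-K1 and H2-D1. Saa1 and Saa2 are therefore not separate measurements with certainty.

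Probe sets above a log2 value of 4 in at least 5 samples were tested, which left 9560 probe sets (42.3%) and 6022 genes. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options) and adjusted by the Benjamini-Hochberg method over all tested probe sets, with an adjusted p under 0.05 taken as a call. Each gene was represented by its tested probe set with the highest mean over all samples. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated, and with fry, over the 29 lists with at least 2 measured members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

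The groups, the tests, 25 pathway lists, 11 marker lists and the rule for named genes were fixed before the data were examined. The named genes are Gsr, the 10 genes with the largest called rise and the 10 with the largest called fall whose groups do not overlap, up to 4 called members of each list or else its member with the smallest p, and a fixed set of genes of glutathione and thioredoxin metabolism. Clone and predicted-gene names were passed over. Alternatives covered filters, scaling, variance models, array weights, a replicate block, thresholds, a test without moderation, other list tests and the omission of each sample in turn. After the data were seen, 2 further alternatives were added: Gsr-null samples 2 and 3 left out together, whose arrays had a higher floor, and a block for a split in the control probe sets described with the results. The pseudocount alternative was not run, since the values are on a log scale.

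The fit was tested on simulated data with the real means and residual spreads over 9560 probe sets. For the Gsr-null against WT comparison it recovered 74.3% of probe sets changed by 1 on the log2 scale and 95.9% of those changed by 2, and 5.61% of its calls had not been planted. In these simulations genes varied independently, which real genes do not, and so the list tests were also set against other splits of the real samples.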

Results

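Glutathione reductase, encoded by Gsr, returns oxidised glutathione to its reduced form with NADPH. Transcript levels were compared in livers of 5 WT and 6 Gsr-null male C57BL/6J mice, 15 to 20 weeks old, harvested between 2 and 4 in the afternoon. Samples resembled each other closely over the tested probe sets, with Pearson's r across probe sets of 0.962 to 0.989 between WT samples, 0.942 to 0.989 between Gsr-null samples and 0.935 to 0.98 between genotypes. The 5th percentile of the log2 values was 1.79 and 1.76 on the arrays of Gsr-null samples 2 and 3, and 1.53 to 1.62 on the others. The 3' minus 5' difference of the Gapdh and Actb control probe sets, a measure of RNA integrity and labelling, parted the samples into 2 sets that crossed genotype. It lay between 0.544 and 0.703 in 2 WT and 3 Gsr-null samples and between 1.2 and 1.75 in 3 WT and 3 Gsr-null samples. The group means did not differ detectably (Gsr-null minus WT -0.21, exact two-sided permutation p = 0.448).

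Gsr itself was lower in every Gsr-null sample than in any WT sample. Its representative probe set averaged 6.82 ± 0.126 (SD, n = 5) in WT and 4.99 ± 0.207 (SD, n = 6) in Gsr-null livers on the log2 scale. Gsr fell by 1.83 on the log2 scale (SE 0.123, limma adjusted p = 1.82e-05). The second tested probe set fell by 1.84 (SE 0.319, limma adjusted p = 0.0331). On the representative probe set every Gsr-null sample stayed above the level of 4 used as a filter, and on the second all but sample 6, at 3.82. The groups did not overlap on either probe set, which matches the labels. Where the probe sets lie relative to the disrupted part of Gsr was not analysed here, so the fall is only a partial check of the labels.

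Against this background 26 genes changed, 13 of them higher and 13 lower in Gsr-null livers. Xdh, the xanthine dehydrogenase of purine breakdown, fell by 2.62 (SE 0.255, limma adjusted p = 0.000448), from 9.35 ± 0.204 (SD, n = 5) to 6.72 ± 0.592 (SD, n = 6). Sae1, a subunit of the SUMO-activating enzyme, rose by 2.05 (SE 0.193, limma adjusted p = 0.0004), and Extl1, a glycosyltransferase of the exostosin family, rose by 1.45 (SE 0.13, limma adjusted p = 0.000315). By probe set, limma called 37 of 9560, with 16 higher and 21 lower, and 36 of the 37 had no overlap between the groups. Among all tested probe sets 1.36% had no overlap, against 0.433% by chance. At an unadjusted p under 0.05 there were 799 probe sets.

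**Figure D1:**
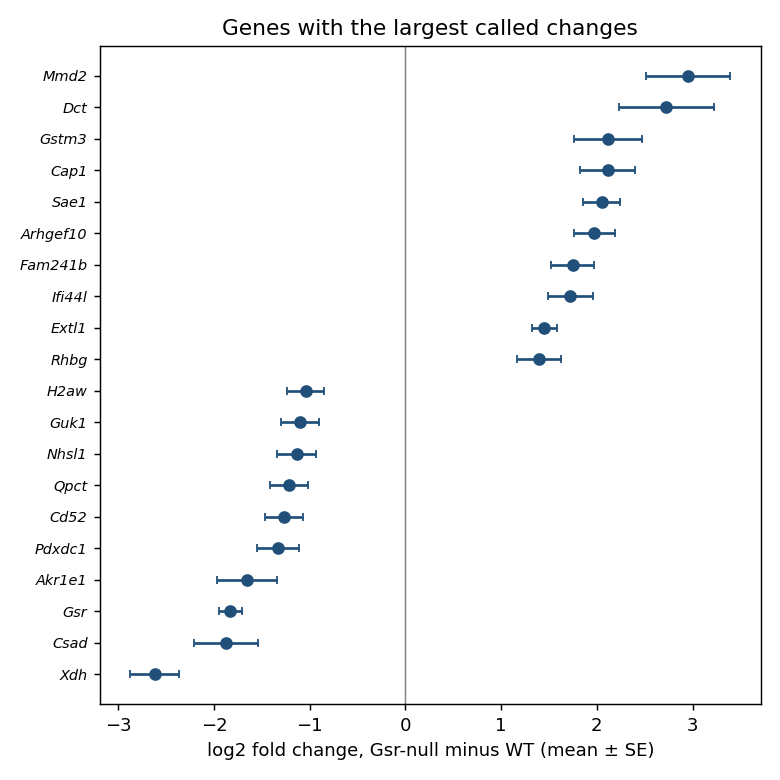
Log2 fold change (Gsr-null minus WT, horizontal axis) of Gsr and the other genes with the largest called changes, each by its representative probe set. Points are means and bars are SE from the limma fit of 5 WT and 6 Gsr-null samples, running from -2.62 for Xdh to 2.95 for Mmd2.

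Among the other genes with the largest rises, Mmd2 rose by 2.95, Dct, the dopachrome tautomerase of melanin synthesis, by 2.73, and Gstm3, a glutathione S-transferase, by 2.11. Cap1, an actin-binding protein, rose by 2.11, Arhgef10 by 1.97, Fam241b by 1.75, Ifi44l by 1.72 and Rhbg, an ammonium transporter, by 1.40. Mmd2, Arhgef10 and Ifi44l averaged 3.64, 2.66 and 2.53 in WT samples, below the level of 4 used as a filter, so their folds start near the floor. Arhgef10 lies on chromosome 8, as does Gsr. Among the falls, Csad, which makes hypotaurine from cysteine sulfinate, fell by 1.87, Akr1e1, an aldo-keto reductase, by 1.65, and Cd52, a leukocyte surface protein, by 1.27. Qpct, a glutaminyl cyclase, fell by 1.22, Nhsl1 by 1.14, Guk1, the guanylate kinase, by 1.10 and H2aw by 1.04. Cd52, Qpct, Nhsl1 and H2aw averaged below 4 in Gsr-null samples, so their folds end near the floor. The limma adjusted p of these 15 genes lay between 0.0011 and 0.0496.

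Pdxdc1 gave opposite answers on its probe sets. Its representative probe set fell by 1.33 (SE 0.22, limma adjusted p = 0.0265), while its other tested probe set was called higher (limma adjusted p = 7.83e-06), from a WT mean of 2.92 near the floor to 6.74. Pdxdc1 therefore has no settled direction here. Of 12 other tested probe sets of 8 called genes, 11 had the sign of the representative one and 9 did so at an unadjusted p under 0.05.

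**Figure D2:**
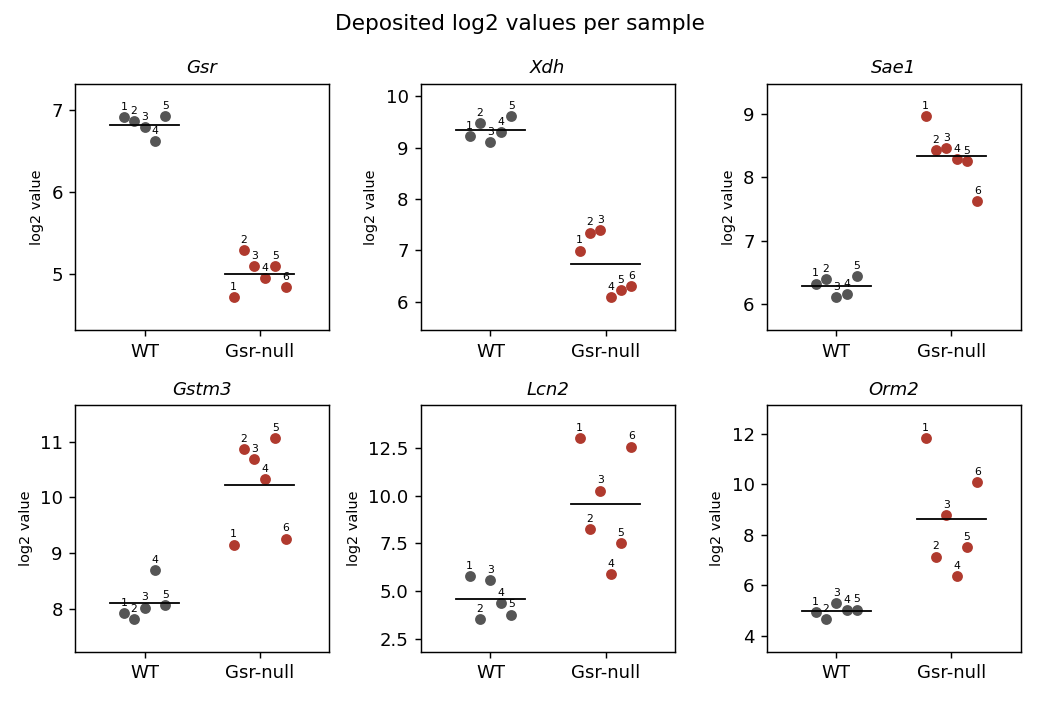
Deposited log2 values (vertical axis) of Gsr, Xdh, Sae1, Gstm3, Lcn2 and Orm2 in 5 WT and 6 Gsr-null samples. Points are samples with their replicate numbers and lines are group means, and for each of these genes every Gsr-null sample lies on 1 side of every WT sample.

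The set of called genes depended on single samples more than the size of the folds did. Of 22 named genes that were called, 8 stayed called whichever sample was left out, namely Gsr, Xdh, Sae1, Extl1, Arhgef10, Cap1, Fam241b and Ifi44l, and 14 lost their call without at least 1 sample. The calls of Dct, Gstm3, Csad, Akr1e1, Nhsl1, Guk1, H2aw and Shmt1 were each lost on leaving out any of at least 7 samples. With the 2 sets of the 3' minus 5' difference as a block, a choice made after the data were seen, limma called 46 probe sets, 35 of them among the 37. Of the 26 called genes 25 stayed called.

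The acute phase proteins, which the liver secretes in inflammation, stood highest among the gene lists. Of 20 measured members 19 had a positive fold and 0 passed the test over all genes, while 5 passed when adjusted over the list alone. Lcn2 was 4.98 higher (SE 1.17, limma adjusted p = 0.145) and Orm2 3.63 higher (SE 0.805, limma adjusted p = 0.112), and in each case every Gsr-null sample lay above every WT sample. Saa1 and Saa2 differed by 2.94 and 3.52, and Orm1 by 0.61. Camera called the list higher (adjusted p = 2.14e-08, adjusted p = 0.816 with an estimated correlation). The mean fold of its members was 1.02 and the median 0.33, with means of 1.62 and 0.485 within the sets of lower and higher 3' minus 5' difference.

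Targets of NRF2, the transcription factor of the electrophile response, had a positive fold in 21 of 26 measured members. Gstm3 rose and was the 1 member called over all genes, and Gstm3 and Ces1g were the 2 called when adjusted over the list alone. Camera called the list higher (adjusted p = 2.91e-05, adjusted p = 0.816 with an estimated correlation). Its mean fold was -0.046 within the set of lower 3' minus 5' difference and 0.526 within the other. The first set held 2 WT and 3 Gsr-null samples and the other 3 and 3. The difference between the sets was not tested, so these means cannot show whether the relation holds in each. Members often used as readouts did not pass the test: Srxn1 differed by 0.50 (limma adjusted p = 0.494), Hmox1 by 0.15, Gclc by 0.13, Gclm by 0.11 and Txnrd1 by -0.0059. Nqo1 did not pass the filter, at 2.75 ± 0.494 (SD, n = 5) in WT and 3.34 ± 0.732 (SD, n = 6) in Gsr-null samples. In Gsr-null samples 4 and 5 Nqo1 was 4.098 and 4.449, above every WT sample, and in the others 2.817 to 3.02. Srxn1 was also highest in samples 4 and 5, at 8.582 and 8.724, against 7.74 to 7.984 in the other Gsr-null samples. Its groups did not overlap. Hmox1, Gclc, Gclm and Txnrd1 in samples 4 and 5 did not exceed their WT values. This unevenness was not tested.

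Genes of superoxide and peroxide removal and metal binding had a positive fold in 11 of 13 measured members, with 0 called over all genes and 1, Mt1, adjusted over the list alone. The metallothioneins Mt1 and Mt2, which bind metal ions, differed by 2.33 and 2.30, whereas Prdx3, Gpx1 and Sod2 differed by 0.23, 0.091 and 0.08. Camera called the list higher (adjusted p = 0.003, adjusted p = 0.24 with an estimated correlation), with means of 0.245 and 0.616 within the sets of lower and higher 3' minus 5' difference. The unfolded protein and integrated stress response list was called higher (camera adjusted p = 0.0225, adjusted p = 0.816 with an estimated correlation) with 0 of 18 members called over all genes or adjusted over the list alone. Its means within the sets were 0.539 and -0.13. The list of pericentral hepatocyte genes was called higher (camera adjusted p = 0.0291, adjusted p = 0.816 with an estimated correlation), and Rhbg was its 1 called member of 9, over all genes and adjusted over the list alone. Its means within the sets were 0.526 and -0.044. None of these 5 list calls held with an estimated correlation, and 51 of 100 splits of the same samples called at least as many lists.

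**Figure D3:**
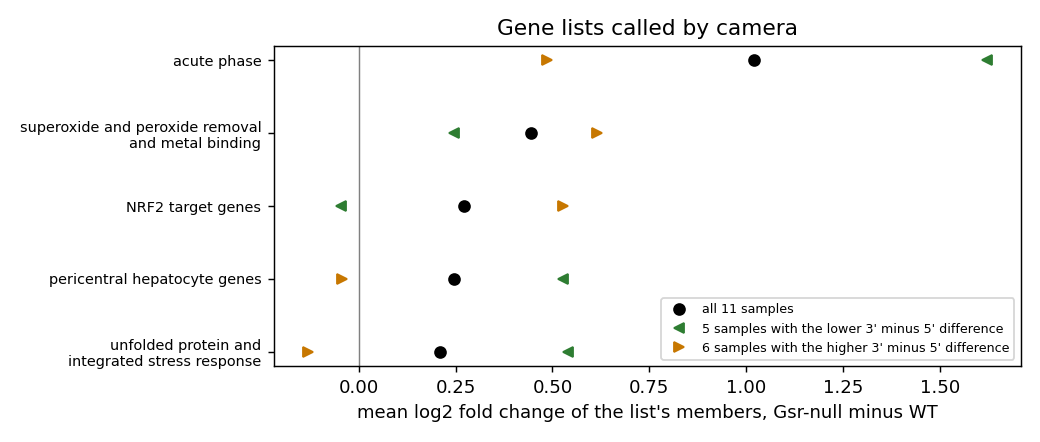
Mean log2 fold change (Gsr-null minus WT, horizontal axis) of the members of the 5 gene lists called by camera, over all 11 samples (circles) and within the samples of lower (left-pointing triangles) and higher (right-pointing triangles) 3' minus 5' difference of control probe sets. The acute phase list lies above 0 in each set, at 1.62 and 0.485, while the NRF2 list lies at -0.046 and 0.526.

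Genes of the methionine cycle, transsulfuration and sulfur oxidation moved in each direction. Of 20 measured members Shmt1, the cytosolic serine hydroxymethyltransferase, rose by 0.66 (SE 0.119, limma adjusted p = 0.0373) and Csad fell, and these 2 were also the ones called when adjusted over the list alone. Fry's test for changes in either direction gave an adjusted p = 0.00017, and camera an adjusted p = 0.513. Cth and Cbs, the enzymes of transsulfuration, differed by 0.41 and -0.19 and did not pass. Among periportal hepatocyte genes Aldh1b1, a mitochondrial aldehyde dehydrogenase, rose by 1.20 (SE 0.178, limma adjusted p = 0.013) and was the 1 member of 10 called (camera adjusted p = 0.27).

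The fixed lists of glutathione synthesis and use and of the thioredoxin system, which hold neither Gsr nor Gstm3, showed no called member, over all genes or adjusted over the list alone. Of 22 measured genes of glutathione synthesis and use, 11 had a positive and 11 a negative fold (camera adjusted p = 0.491), and Glrx, glutaredoxin, differed by 0.86 (limma adjusted p = 0.269). The 18 genes of the thioredoxin, peroxiredoxin and methionine sulfoxide reductase system gave a camera adjusted p = 0.423, with Txn1 at 0.034 and Rrm2, a subunit of ribonucleotide reductase, at -1.15 (limma adjusted p = 0.36). NADPH supply gave a camera adjusted p = 0.335, with Nnt, the mitochondrial transhydrogenase, at 0.55. Selenoproteins gave 0.491, with Txnrd3 at -0.39, and iron and heme handling 0.491, with Tfrc at 0.88.

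No member was called in the lists of lipid, drug and glucose metabolism. Camera adjusted p values were 0.205 for cholesterol synthesis (Stard4 -0.65), 0.998 for fatty acid and triglyceride synthesis (Lpin1 -0.79), 0.27 for fatty acid oxidation and PPAR-alpha targets (Vnn1 -3.43, SE 1.26) and 0.491 for CAR, PXR and AHR targets (Cyp2c37 -0.71). They were 0.423 for bile acid synthesis and transport (Slco1a1 -0.80), 0.495 for glucose handling (Gys2 -0.53), 0.423 for the circadian clock (Cry1 0.86) and 0.998 for male-biased genes (Cyp4a12a 0.57). The female-biased list had 1 measured member, Acot3 (-0.18). The fold of Vnn1 was uneven among the Gsr-null samples. Vnn1 was 3.15 to 4.26 in samples 1, 2, 3 and 6, near the filter level of 4. In samples 4 and 5 it was 10.55 and 9.60, near the WT values of 8.84 to 10.05. Stress and growth lists were also without a called member: heat shock (camera adjusted p = 0.66, Hsp90aa1 0.37), interferon response and antigen processing (0.105, Igtp 0.67), p53 targets (0.998, Fas 0.45) and cell cycle (0.423, Rrm2 -1.15). Median, mean and camera direction differed in sign for the glutathione, thioredoxin, methionine, iron, heat shock and hepatocyte lists, all of them uncalled by camera.

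Markers of other cell types gave no called member. Camera adjusted p was 0.983 for hepatocytes (Ahsg -0.11), 0.998 for Kupffer cells and macrophages (Cd68 0.32), 0.498 for sinusoidal endothelium (Fcgr2b -0.38) and 0.27 for stellate cells and fibroblasts (Col1a2 0.89). Neutrophil and erythroid lists had 1 measured member each, Lyz2 (-0.40) and Alas2 (0.59), and those of cholangiocytes, B cells, T and NK cells, adipocytes and acinar cells had 0. Among the 25 measured genes on each side of Gsr, in the order of assembly GRCm38.p6, 0 of 50 were called by limma against 25 of 5971 others (Fisher's exact p = 1), with 7 at an unadjusted p under 0.05. Of all 9560 tested probe sets, 799 reached that p. With 50 genes on each side, 1 of 100 was called, Arhgef10 (Fisher's exact p = 0.343).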

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

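Of the tests below, those on S100a8 and S100a9, and those of the acute phase mean against its SE, without Gsr-null samples 2 and 3 or with the 3' to 5' sets as a block, were chosen only after the acute phase values had been seen. The splits of the samples, the omission of Gsr-null samples 2 and 3 and the control probe sets were chosen before their results were seen.

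In 7 of 122 groups of values 1 sample stood far from the rest, where chance would give 6.1. Gstm3 was 8.71 in WT sample 4, against 7.83 to 8.07 in the others, and Qpct 4.91 in the same sample, against 4.19 to 4.36. Qpct was 2.47 in Gsr-null sample 3, against 3.17 to 3.53. Gys2 was 10.5 in WT sample 1 and Hsp90aa1 10.4 in WT sample 2. In Gsr-null sample 6 Gclc was 9.79, and 9094 probe sets were above the log2 value of 4, against 9459 to 9551 in the other Gsr-null samples.

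Chance is argued against for the number of probe sets called. Of 100 splits drawn from the 462 possible, 1, the real one, called 37, and the highest of the others called 16. The splits not drawn were not examined, and splits cannot tell genotype from other differences between the groups. Chance cannot be excluded for the number of lists, since 51 of 100 splits called at least the real 5 and the highest called 12.

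The acute phase list was higher in Gsr-null livers by camera (adjusted p = 2.14e-08; adjusted p = 0.816 with an estimated correlation), but unevenly: Lcn2 was 13.0, 12.6 and 10.3 in Gsr-null samples 1, 6 and 3 and 5.91 in sample 4. Chance is not excluded, because 16 of 100 splits gave a camera p as small, the highest -log10 p among the others being 18.3 against the real 9.13. RNA integrity as the whole source is argued against by the block for the 3' to 5' sets, with which the list's mean was 0.988, or 2.60 times its SE. A part stays open, as the 3' minus 5' difference between genotypes (exact permutation p = 0.448) had an SE of 0.271 and the list's mean was 1.62 in the lower and 0.485 in the higher set. In samples 3 and 6 S100a8 was 3.63 and 3.26, against 2.53 to 3.16 in WT, and S100a9 was 3.13 and 3.49, against 2.81 to 3.14. All lay below the filter level of 4, so they cannot decide on neutrophils there. Leaving out Gsr-null samples 2 and 3 gave their higher floor little support, since the list's mean moved only from 1.02 to 0.972 (adjusted p = 1.22e-05), but the floor is not excluded, as that mean was 1.93 times its SE with a variance for each genotype and 2.16 times with a pooled one. More neutrophils or monocytes stay open for samples 1, 3 and 6, S100a8 reaching 6.63 in sample 1, and a response of the genotype remains untested beyond the comparison itself.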

How the results depend on the processing

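Leaving out Gsr-null samples 2 and 3, and the block for the 3' to 5' sets, were chosen after the data were seen, and the other alternatives before. Gsr, the disrupted gene, stayed called under all of them, at -1.93 to -1.77. Of 751 values of 55 other named genes under alternatives, 692 kept their direction and side of the threshold, 57 lost a call and 1 gained one; Pdxdc1 reversed to 1.25 with the mean of its probe sets, which move in opposite directions. Genes near the floor limit what low signals can show, and the causes of the changes below were not tested except where fewer probe sets, fewer samples or a stricter threshold enter by construction. Counts of called probe sets, 16 higher and 21 lower, became 7 and 7 with the filter at a log2 value of 6, where fewer probe sets are tested, 6 and 4 without Gsr-null samples 2 and 3, 7 and 5 at an adjusted p under 0.01, and 6 and 4 with a plain two-sample test without moderation. Called genes, 13 higher and 13 lower, became 6 and 6 with that filter and 5 and 4 without those 2 samples. Leaving out 1 sample gave 9 to 24 probe sets higher and 5 to 19 lower, and 8 to 16 genes higher and 3 to 14 lower. The count of higher genes moved by over 1.5 times without WT sample 5, and that of lower genes without any of the 5 WT samples or Gsr-null samples 2 or 3. Among neighbours of Gsr, 1 gene, Arhgef10, was called with 50 on each side, where more genes enter.

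The replicate numbers shared by the genotypes do not pair the samples: deviations of same-numbered samples correlated at -0.173, 0.036, -0.056, -0.243 and -0.171, and 0 of 5 WT samples correlated best with their own number. With the number as a block, over replicates 1 to 5, limma called 2 probe sets higher and 1 lower, and 1 gene higher and 1 lower, and the stress response and pericentral lists had adjusted p values of 0.096 and 0.0743.

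The list for the unfolded protein and integrated stress response lost its call with no filter (0.349), the filter on the mean (0.0852), quantile normalization (0.0615), array weights (0.25), the 3' to 5' block (0.0593) and without Gsr-null samples 2 and 3 (0.745), with a range of 0.000208 to 0.242 when 1 sample was left out and the call lost without WT sample 1 or Gsr-null samples 1, 2, 3 or 6. The pericentral list lost it with no filter (0.442), the filter at 6 (0.261), the filter on the mean (0.112), quantile normalization (0.0615), array weights (0.13), the 3' to 5' block (0.0697) and without those 2 samples (0.341), with a range of 0.00355 to 0.205 and the call lost without the same single samples. Superoxide removal and metal binding lost it with no filter (0.0631). The interferon list became called lower with no filter (0.000407), the filter on the mean (0.018), array weights (0.0172) and without Gsr-null samples 2 and 3 (0.00363), with a range of 0.0207 to 0.415 and a call without WT sample 2, WT sample 4 or Gsr-null sample 2. Leaving out 1 sample gave 0.00831 (without WT sample 4) to 0.571 for cholesterol synthesis and 0.00565 (without Gsr-null sample 4, with a call also without sample 5) to 0.598 for fatty acid oxidation. With an estimated correlation camera gave adjusted p values of 0.816 for the NRF2, acute phase, stress response and pericentral lists and 0.24 for superoxide removal. Fry's one-way test gave 0.732 for NRF2, acute phase and pericentral, 0.774 for stress response and 0.0982 for superoxide removal. Its test in either direction gave 0.0733 for NRF2 and pericentral, 0.0738 for acute phase, 0.606 for stress response, 0.125 for superoxide removal and 0.00017 for the methionine list, the 1 list it called.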

Other observations

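The tests of Sparc and the collagens, of the 3' to 5' block, of the MHC genes, of shuffled positions, of other probe sets and of the odds ratio's limit around Gsr were chosen only after the values had been seen, while those of other splits and gene families and Fisher's test around Gsr were chosen before.

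Outside the fixed lists, Sparc, a matrix-associated protein, rose by 0.94 (SE 0.139, limma adjusted p = 0.013), and Col4a1 and Col4a2, the chains of basement membrane collagen, differed by 1.01 and 0.98 without passing the test. With the 3' to 5' sets as a block, Cnot8, Aldh4a1 and Ces1g, the last a member of the NRF2 list, were called higher, at 0.78, 0.76 and 1.35, and Foxred1, Prkd3 and Ift27 lower, at -0.58, -0.87 and -0.83, though not without it by their representative probe sets. These genes were chosen after their values were seen.

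The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 differed by -1.19, -0.98 and -1.03, none passing the test (limma adjusted p = 0.102, 0.137 and 0.282). A loss of macrophages as the whole cause is argued against by the macrophage markers, whose median lay 0.927 above that of the class II genes, against a spread (SD) of 0.209 among 9 markers. That spread is between markers, not samples. The mean of these markers differed by 0.455 within the set of lower 3' minus 5' difference and by -0.545 within the other, so a part stays open. Different MHC alleles that bind the probes less stay open: Cd74, on another chromosome, was also lower, at -0.837 (unadjusted p = 0.0174, limma adjusted p = 0.443), but so were the class I genes H2-K1 and H2-D1 of the MHC (limma adjusted p = 0.258 and 0.443), only in Gsr-null samples 1, 3, 5 and 6, at 10.2 to 10.5 and at most 11.2, while samples 2 and 4, at 11.1 to 11.2 and 11.7 to 11.9, lay at the WT level of 11.1 to 11.4 and 11.6 to 12.0. Another probe set of H2-D1, which can bind related genes, parted the same samples, at 10.4 to 11.7 against 5.55 to 6.06 in samples 2 and 4 and 5.30 to 6.80 in WT, while H2-Aa was below its WT range of 8.06 to 8.73 in all Gsr-null samples. Whether all Gsr-null mice carried the same MHC alleles was not tested, and this split of the class I values leaves it open. Lower numbers of B cells or dendritic cells remain open, since no B cell marker passed the filter.

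Genes with small p values often seemed to lie side by side, such as Xdh, Ttc27, Fez2, Prkd3 and Qpct on chromosome 17. So did Sparc, Cnot8, H2aw and Guk1 and, apart from these, Flii and Shmt1 on chromosome 11. Col4a1 and Col4a2 were neighbours on chromosome 8. Of the 100 genes with the smallest p, 38 had another within 10 measured genes, against a mean of 27.8 when positions were shuffled (permutation p = 0.0468). The pattern was not established. With 1 gene of each family, 31 of 96 genes had such a neighbour, against a mean of 25.8 in the shuffles (permutation p = 0.199). The shuffled sets were not thinned by family, which raises that p, so it cannot decide whether the pattern exists. Of 100 splits of the samples 9, the real one among them, gave as many neighbours, up to 42. The splits thus did not tie the pattern to genotype, but they cannot show that genotype plays no part. Variants under single probe sets could be examined only for the 17 of these 38 genes with another tested probe set. Of 21 such probe sets, 12 (57.1%) moved the same way at an unadjusted p under 0.05. That argues against variants for the genes of those 12 probe sets alone. Variants stay open for the rest, among them Pdxdc1, whose tested probe sets moved in opposite directions. None of this bears on whether the pattern exists. DNA of another strain retained around Gsr cannot be told apart from its absence, as 0 of 50 genes there were called (Fisher's exact p = 1) and the upper limit of the odds ratio was 19.6. With 50 genes on each side Arhgef10 was called, and the odds ratio was 2.48 (limits 0.0598 to 15.5). Retained DNA therefore stays open for the rise of Arhgef10 too.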
